A study of Mus musculus with 6 samples.

How the data were processed

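RNA from whole kidneys of mouse embryos at embryonic day 16 was sequenced in 6 libraries. The labels place 3 libraries in a control group (wild type, miR-17~92 flx/+) and 3 in a mutant group (Six2-TGC; miR-17~92 flx/flx), in which the Six2-TGC transgene drives Cre recombinase in nephron progenitors and removes the floxed microRNA cluster there. The labels also give each library a litter, so that each of 3 litters supplied 1 control and 1 mutant library. RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit. The kit does not retain RNA as short as mature microRNAs, and the strand setting is not given.

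The deposited table holds CPM values, read counts scaled by the authors to the library total, from reads aligned with TopHat2 2.0.9, with Picard, SAMtools and build NCBIM37 also named in the submitters' processing notes. The counting program and the gene annotation are not stated. Every CPM value in the deposited table is a whole number of reads, within 0.001 reads, of a library total between 43804667 and 54913325 reads. The rows listed leave out 0.105% to 0.117% of each total, so genes below some minimum had been removed after scaling. Of the 13965 rows, 526 join more than 1 Ensembl identifier, which is how the authors treated overlapping genes, and 217 of these join at least 2 protein-coding genes. A value in such a row cannot be assigned to either gene. Symbols came from the GENCODE M21 annotation for 13695 rows, and 270 rows matched no symbol. One CPM stands for 44 to 55 reads, depending on the library. The 10 most abundant rows took 2.39% to 2.61% of the reads. Intervals for ratios of reads are exact binomial intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

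Genes were compared with limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), with the mean-variance trend on, for the 13766 rows with at least 1 CPM in at least 3 libraries. P values were adjusted by the Benjamini-Hochberg method over these rows, and a row was called at an adjusted p below 0.05. The model held genotype alone. The same model with litter as a block (paired by litter) was the alternative named for every result. Across genes, deviations from the group means of control and mutant libraries correlated at 0.619, 0.446 and 0.312 within the 3 litters named by the labels, and at -0.514 to 0.172 between libraries of different litters. Genes are not independent replicates in these correlations. No pair of libraries in a group differed by as little as read sampling would give, with a chi-square per degree of freedom of 21.6 to 51.1. Single values were compared with exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1.

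The model was tested on simulated data with the library totals of the table and a litter effect. Without the block, limma recovered 78.3% of genes changed by 1.5-fold, 99.4% of those changed by 2-fold and 100% of those changed by 3-fold, and 0% of its calls were false. With the block, these shares were 97.0%, 100% and 100%, and 3.69% of the calls were false. Sets of 30 genes shifted by 0.3 on the log2 scale had an unadjusted p below 0.05 by camera in 5 of 5 simulations, and sets that did not shift in 0. The run was set to stop unless every shifted set passed. Genes were drawn independently of each other, with no trend on length or GC content. These sets therefore cannot show how often camera calls a list falsely in the real data, where genes of a list are correlated.

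Lists of genes were fixed before the data were examined, 31 in all. They covered the targeted locus and its neighbour, Six2 and its neighbours, kidney lineages (nephron progenitor, early nephron, podocyte, proximal tubule, loop and distal tubule, ureteric bud and collecting duct, urothelium, stroma, endothelium), other cells and adhering tissues (macrophage and leukocyte, erythroid, adrenal, gonad, skeletal muscle, liver, neural and Schwann), and reported targets of the cluster. The remaining lists covered proliferation, p53 and apoptosis, tubular injury, cystic kidney disease, hypoxia and glycolysis, extracellular matrix, the renin-angiotensin system, immediate early and heat shock genes, sex, replication-dependent histones, mitochondrial transcripts and ribosomal proteins. The 29 lists with enough rows were tested as sets with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry, which tests whether a set's genes move on balance in one direction. With an estimated correlation camera also takes its degrees of freedom from the residuals of the model, which are few with 6 libraries. A call lost there therefore need not come from correlation between genes. Members called were also counted with p values adjusted over the list alone.

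Sites for the 4 seed families of the cluster (miR-17/20a, miR-18a, miR-19 and miR-92a) were searched as 7-base matches to microRNA bases 2 to 8 in the longest annotated 3' UTR of each gene, from GENCODE M21 transcripts, where it was at least 50 bases long. A site of 8 bases adds an A after the match. In all, 12984 rows were searched. Transcript length and GC content were those of the longest annotated transcript of each gene. Genes with a site were set against tested and searched genes without one by camera, and the difference of their median log2 fold changes was set against 50 control 7-mers per family of the same base composition, with a number of genes with a site within 20% of the family's. The p values of the 5 sets of 7-base sites (4 families, and any of them) were adjusted together. This separate adjustment was adopted after values adjusted over the 7-base and 8-base sets together had been seen, and both are given where they differ in call.

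Genes named in the text were chosen by a rule written before the data were examined. It took Mir17hg, Six2, Six3 and Cftr whatever their test, and the 10 genes with the largest and the 10 with the most negative change among called genes with a mean of at least 1 CPM and no overlap between the groups. It also took up to 3 members of each list with the smallest unadjusted p. Other members of a list that are named were chosen after their values were seen.

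Alternatives were a pseudocount of 0.1 or 1, no filter, a filter of 5 CPM, median-ratio and trimmed-mean scaling, the variance trend off with robust fitting, each library or litter left out, the litter block, 8-base sites, and genes matched on 3' UTR length. Alternatives chosen after seeing the data were limma's voom on the recovered reads with and without the block, removal of each library's smooth trend on transcript length and GC content with and without the block, the block with median-ratio scaling, the block on litters 2 and 3 alone, an estimated correlation for the seed sites, and their adjustment over both site lengths. Other software was statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparison itself.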

Results

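Gene expression was measured by RNA sequencing in whole mouse kidneys at embryonic day 16, in 3 control and 3 mutant libraries. By genotype, mutant kidneys had lost both copies of the miR-17~92 microRNA cluster in nephron progenitors, the cells that express the Six2-TGC Cre transgene. Cells that descend from these progenitors inherit the deletion. Control kidneys carried 1 floxed copy and, by their label, no transgene. Each of 3 litters gave 1 control and 1 mutant library. The control libraries held 43804667, 44011788 and 49473404 reads in litters 1, 2 and 3, and the mutant libraries 48304108, 54913325 and 46672915. The series title asks which genes differ in nephron progenitors that lack the cluster. The RNA came from whole kidneys, so progenitors gave only a part of it. In a principal component analysis, the first component (36.1% of the variance) set both libraries of litter 1 apart, and the second (31.9%) parted mutant from control kidneys.

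The primary transcript of the deleted cluster was still detected in mutant kidneys, with a higher mean than in controls. The deposited row holds Mir17hg, the host transcript, joined with the overlapping microRNA genes, so its reads cannot be placed inside or outside the deleted segment, and mature microRNAs are too short for the library kit. It stood at 31.2 ± 7.18 CPM (SD, n = 3) in control and 46.0 ± 7.01 CPM in mutant kidneys, and was higher in 3 of 3 litters. The log2 difference of 0.57 (SE 0.17) had an adjusted p of 0.222, and of 0.0292 when paired by litter. Over the alternatives for the targeted locus the adjusted p ranged from 0.0230 to 0.914, and the difference was 0.37 without control library 3. The exact permutation p for these 3 and 3 values was 0.1, the smallest possible. Gpc5, the neighbouring gene, stood at 2.89 ± 0.419 CPM in control and 4.39 ± 0.436 CPM in mutant kidneys, with an adjusted p of 0.199, and of 0.0418 when paired by litter. Adjusted over the list alone, both measured members of this list rose.

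Six3, a homeobox gene beside Six2, was almost silent in control kidneys and expressed in every mutant kidney. It had 0, 2 and 0 reads in the control libraries and 738, 1104 and 823 reads in the mutant libraries, or 15.3, 20.1 and 17.6 CPM. The ratio of the summed reads, each sum divided by its group's total, was 1220, with a counting interval from 338 to 10083, and the adjusted p was 1.34e-07 (1.61e-06 when paired by litter, and 1.27e-09 to 4.84e-05 over all alternatives in which it was tested). Six2, the transcription factor that maintains nephron progenitors and whose promoter drives the Cre transgene, stood at 50.6 ± 7.95 CPM in control and 38.6 ± 6.68 CPM in mutant kidneys and was lower in 3 of 3 litters. Its log2 change of -0.39 had an adjusted p of 0.354, and of 0.00626 when paired by litter. The other 5 measured neighbours of Six2 were not called, with changes between -0.06 for Ppm1b and 0.13 for Camkmt, and the list as a set had an adjusted p of 0.162 by camera and passed by fry (0.000118, and 0.0525 paired). The set holds Six3 itself. Of its 7 members 4 had a change above 0 and 3 below, with a median of 0.096, so the fry result does not show a shift of the whole locus. The control label names no Six2-TGC, and if these kidneys lacked it, effects of the transgene and of the deletion are confounded in every gene reported here.

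**Figure D1:**
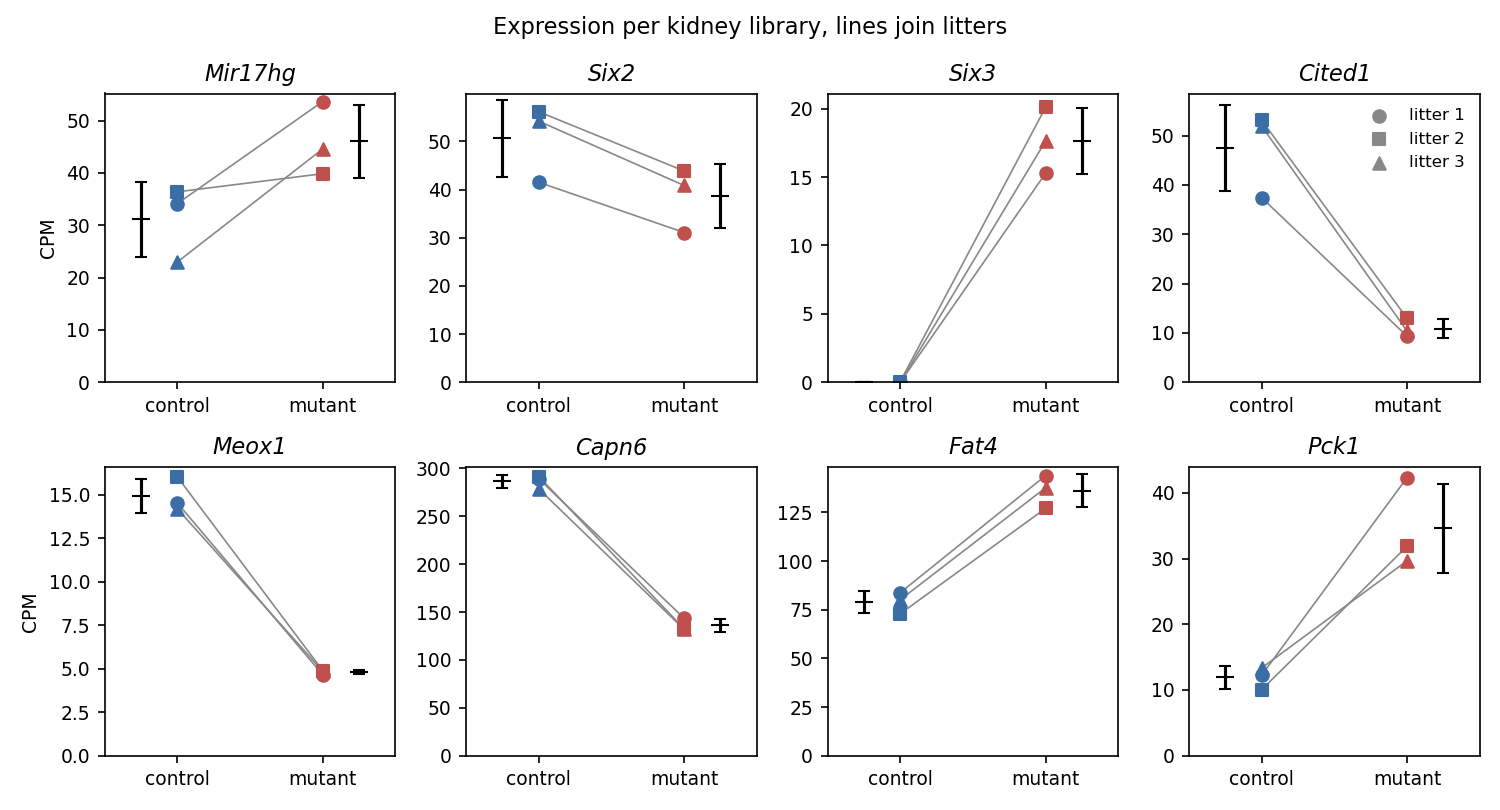
Expression (CPM) of 8 genes in each kidney library, with a line joining the control and mutant library of each litter, and the mean and SD (n = 3) of each group in black beside the points. Six3 lies at or near 0 CPM in the control kidneys and at 15.3 to 20.1 CPM in the mutant kidneys, and Cited1, Meox1 and Capn6 are lower and Fat4 and Pck1 higher in each mutant library than in each control library.

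Genes that mark uncommitted nephron progenitors were among the largest losses in mutant kidneys, and 77 genes differed in the model of genotype alone, 50 of them higher and 27 lower. Cited1, a transcriptional co-activator that marks the early cap mesenchyme, fell from 47.5 ± 8.73 to 10.9 ± 1.87 CPM (log2 change -2.07, adjusted p = 0.000224). The homeobox genes Meox2 (from 12 to 1.77 CPM, log2 change -2.47) and Meox1 (from 14.9 ± 0.976 to 4.81 ± 0.130 CPM, log2 change -1.54) fell as well, and so did Traf1, an adaptor of tumour necrosis factor receptors (from 17.3 to 5.28 CPM), and Snap91, a clathrin assembly protein (from 33.4 to 11.4 CPM). Siglecg, a sialic acid-binding lectin best known from B cells, had 522 reads in the 3 control libraries and 19 in the 3 mutant libraries. Lower levels were also called for Klhdc8a, Lamp5, Col11a2 (a type XI collagen chain) and the joined row named Galnt15, with log2 changes of -1.61, -1.57, -1.45 and -1.70. Among genes with a mean of at least 1 CPM, those that rose most after Six3 were Cnmd, the cartilage glycoprotein chondromodulin (log2 change 1.69), Adcy8, an adenylyl cyclase (1.58), and Pck1, a gluconeogenic enzyme made in proximal tubules (from 11.9 ± 1.68 to 34.6 ± 6.76 CPM, 1.49, adjusted p = 0.00257). Col6a5 (1.35), the AMPA receptor subunit gene Gria1 (1.31), Itih2 (1.27), Grid1 (1.19), Ano3 (1.15) and Kirrel3 (1.12) rose too.

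Changes of at least 1 on the log2 scale made up 14 of the genes that rose, and 18 fell by as much or more. Paired by litter, limma called 1574 genes, 1091 higher and 483 lower, among them all 77, with smaller median changes of 0.32 for higher and -0.23 for lower genes (0.78 and -1.16 unpaired). These paired calls were 11.4% of all tested rows, the share to hold against paired counts of list members. With median-ratio scaling the paired counts were 909 higher and 593 lower, so the share of higher genes went from 69.3% to 60.5%. The unpaired count was 27 (14 higher, 13 lower) without control library 2, 44 (25 higher, 19 lower) without control library 3, 34 (13 higher, 21 lower) without mutant library 2 and 22 (7 higher, 15 lower) without mutant library 3. It was 6 without litter 2 and 1 without litter 3, where 868 and 754 genes had an unadjusted p below 0.05 by limma. With each of the 6 libraries left out in turn, Cited1, Meox1, Meox2, Traf1, Capn6, Snap91, Klhdc8a, Lamp5, Pck1, Adcy8, Fat4 and Ntn1 were called each time. Siglecg was called in each of the 3 such comparisons in which it could be tested. Of the 28 called genes chosen by the rule, 17 of 26 tested were still called without control library 2, 20 of 26 without control library 3, 17 of 27 without mutant library 2 and 15 of 27 without mutant library 3, against 25 of 26 and 23 of 27 without control library 1 and mutant library 1.

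Nephron progenitor genes were lower as a group, with the losses in part of the list. Of 21 measured members 4 fell and 1 rose, and 16 did not pass. Adjusted over the list alone, 8 fell and 1 rose, and paired by litter 11 fell and 1 rose. Beside Cited1, Traf1 and Meox1, the gene that fell was Capn6, a member of the calpain family, which went from 286 ± 6.89 to 136 ± 6.51 CPM (log2 change -1.07, adjusted p = 0.000172). The member that rose was Fgf20, a growth factor made by the progenitors themselves, from 1.79 to 3.43 CPM (adjusted p = 0.0465, 0.0108 paired). Without the block, Fgf20 lost its call with any single library left out. Its adjusted p was then 0.0571, 0.139 and 0.138 without control libraries 1, 2 and 3 and 0.0799, 0.149 and 0.208 without mutant libraries 1, 2 and 3. Gdnf, Itga8 and Hoxa11, also of this list, had log2 changes of 0.00, 0.01 and -0.02. The median change was -0.25, and the list passed camera with an adjusted p of 8.07e-10 (4.32e-08 paired by litter). With an estimated correlation its adjusted p was 0.0920.

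Genes of the early nephron, the podocytes and the ureteric bud passed in both directions when paired by litter. In the early nephron list none of 24 members passed unpaired, 3 rose and 3 fell adjusted over the list alone, and 6 rose and 3 fell paired by litter. Among these, Cdh6 stood at 23.8 ± 3.97 CPM in control and 36.9 ± 2.19 CPM in mutant kidneys (adjusted p = 0.0663, 0.00471 paired), and Tmem100 at 14.4 ± 2.41 and 8.87 ± 0.308 CPM (0.0716, 0.00878 paired). As a set the list was not called (camera adjusted p = 0.889). Of 21 podocyte genes 1 rose, Npnt, an extracellular ligand of integrin alpha 8 (from 313 to 417 CPM, adjusted p = 0.0496, 0.00246 paired). With each of the 6 libraries left out in turn and no block, Npnt was called 1 time, with an adjusted p up to 0.192. Adjusted over the list alone 3 podocyte genes rose, and the set was not called (camera adjusted p = 0.330). Paired by litter 5 podocyte genes rose, among them the basement membrane collagens Col4a3 and Col4a4, and 2 fell. In the ureteric bud and collecting duct list 0 of 25 genes passed unpaired, 1 rose and 2 fell adjusted over the list alone, 5 rose and 2 fell paired by litter, and the set had an adjusted p of 0.294. With the length and GC correction the set passed, with a median of 0.17 and an adjusted p of 0.0488, but not with the block as well (0.0726, or 0.617 with an estimated correlation). Etv4, a transcription factor active in ureteric tips and nephron progenitors, stood at 105 ± 12 CPM in control and 74.7 ± 4.45 CPM in mutant kidneys (adjusted p = 0.0749, 0.00208 paired).

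Proximal tubule genes were higher as a group. Of 37 members none was called unpaired, 2 rose adjusted over the list alone, and 9 rose paired by litter. They include Keg1 (44.6 ± 4.29 CPM in control and 67.8 ± 7.90 CPM in mutant kidneys, adjusted p = 0.00219 paired), the endocytic receptor gene Lrp2 (332 ± 30.7 and 479 ± 67.0 CPM, 0.00649 paired) and the water channel gene Aqp1 (43.8 ± 3.04 and 56.1 ± 3.52 CPM, 0.0149 paired). With the block and the length and GC correction 5 members rose, and Lrp2, with a log2 change of 0.27 in place of 0.52, was not among them (adjusted p = 0.114). The median log2 change was 0.19, and camera gave an adjusted p of 0.000542 (0.00213 paired), or 0.563 with an estimated correlation. This call was lost without mutant library 1, where the median was 0.07 and the adjusted p 0.233, without litter 1 (0.08 and 0.259), and on litters 2 and 3 with the block (adjusted p = 0.281). The loop and distal tubule list leaned the other way, with a median of -0.19 over 19 members, 0 of them called unpaired over all genes or adjusted over the list alone, and an adjusted p of 0.0449. This became 0.601 with an estimated correlation, 0.0792 paired by litter, and 0.0789, 0.146 and 0.568 without control library 1, control library 3 and mutant library 3. The median was -0.03 without mutant library 3 and -0.0002 without litter 3 (adjusted p = 0.858). The call was also lost with median-ratio (0.0547) and trimmed-mean (0.0532) scaling and with the length and GC correction (0.137, or 0.147 with the block as well). Paired by litter, 2 of these genes fell and 1, Trpm6, rose.

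Genes of the stroma and of the extracellular matrix were higher in mutant kidneys. Fat4, an atypical cadherin of the renal stroma, rose from 78.9 ± 5.51 to 136 ± 8.52 CPM (adjusted p = 0.00456), Ntn1, a secreted guidance cue, from 70.9 ± 3.52 to 114 ± 4.19 CPM (0.00631), and Pdgfra, a growth factor receptor of mesenchymal cells, from 195 ± 18.0 to 278 ± 19.3 CPM (0.0381). These were the 3 of 21 stromal genes called, 0 fell, and 7 rose adjusted over the list alone. Paired by litter 9 rose and 1 fell, Rgs5, a gene of pericytes, which stood at 87.2 CPM in control and 64.4 CPM in mutant kidneys (adjusted p = 0.601, 0.0496 paired, and 0.0904 paired with the length and GC correction). The smooth muscle genes Acta2 and Tagln had log2 changes of 0.02 and -0.03. The stromal median was 0.30 (camera adjusted p = 7.81e-07, 8.75e-06 paired), with an adjusted p of 0.0920 with an estimated correlation. All 26 extracellular matrix genes had a positive change. Fibronectin (Fn1, from 636 ± 49.8 to 881 ± 51.5 CPM) and fibrillin 1 (Fbn1, from 192 ± 3.75 to 270 ± 26.3 CPM) rose, 19 rose adjusted over the list alone, and 20 rose paired by litter, with 0 lower. Their median was 0.30 (camera adjusted p = 1.03e-16, 7.25e-16 paired), or an adjusted p of 0.195 with an estimated correlation. Paired by litter, Fn1, Fbn1 and Pdgfra had an adjusted p of 0.000918, 0.00332 and 0.000946. With each of the 6 libraries left out in turn and no block, these genes were called 2, 0 and 1 times. Their adjusted p then went up to 0.171, 0.139 and 0.148.

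**Figure D2:**
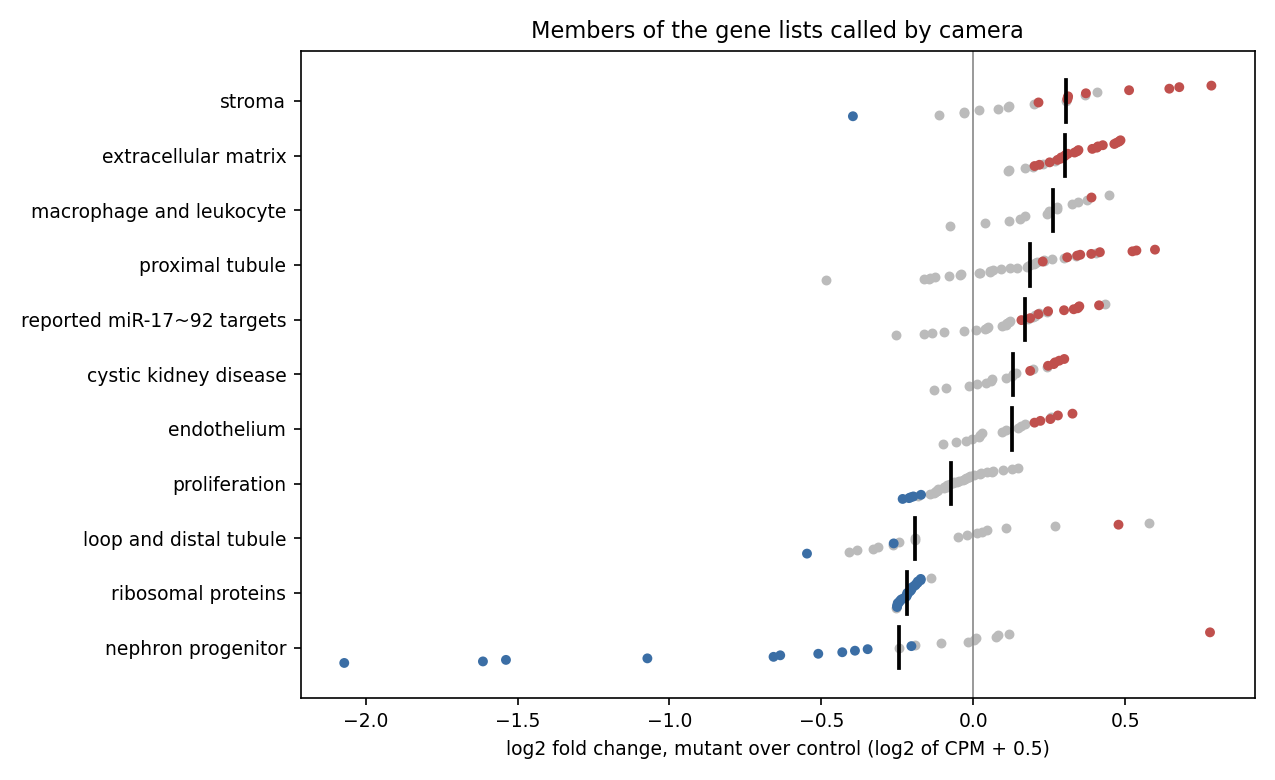
Log2 fold change (mutant over control, from log2 of CPM + 0.5) of each member of the 11 gene lists called by camera, 1 point per gene, ordered by change within a list, with the list's median as a black bar. Red and blue points passed the paired limma test as higher or lower and grey ones did not. Medians run from -0.25 for nephron progenitor genes to 0.30 for stromal genes.

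Ribosomal protein genes were lower by a small and even amount. All 25 had a negative change, with a median of -0.22 on the log2 scale, 0 were called over all genes, 20 fell adjusted over the list alone, and 23 fell paired by litter. Rpl3 stood at 1244 ± 32.0 CPM in control and 1069.7 ± 35.1 CPM in mutant kidneys (adjusted p = 0.170, 0.00922 paired). The set had an adjusted p of 6.16e-18 by camera (2.23e-19 paired) and of 0.308 with an estimated correlation. These messages are short, with a median transcript of 1151 bases against 5912.5 bases for the extracellular matrix list, and the change in mutant kidneys followed length across all genes.

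Long transcripts were higher and short transcripts lower in mutant kidneys. Across genes, which are not independent replicates, Spearman's rho between transcript length and log2 fold change was 0.413. Median changes ran from -0.10 in the shortest decile to 0.17 in the longest. Genes called higher had a median transcript of 5797 bases and genes called lower 3083 bases, against 3445 bases for all tested rows. The relation of expression to length in each library, as rho of its deviation from the mean of all libraries, was -0.0773, -0.425 and -0.133 in control libraries 1, 2 and 3 and 0.233, -0.0386 and 0.446 in mutant libraries 1, 2 and 3. In each litter it was higher in the mutant. After each library's trend on length and GC content was removed, rho was 0.0209, and the paired test called 828 genes, 479 higher and 349 lower, among them all 77. The extracellular matrix and ribosomal medians were then 0.19 and -0.15, the stromal median 0.20, and the nephron progenitor median -0.26, and these 4 lists still passed camera at the preset correlation. With an estimated correlation none did, with an adjusted p of 0.518, 0.448, 0.451 and 0.448. By fry, with the block and the correction, nephron progenitor (adjusted p = 0.0259) and ribosomal proteins (0.0262) passed. Stroma (0.0651) and extracellular matrix (0.146) did not pass fry there.

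**Figure D3:**
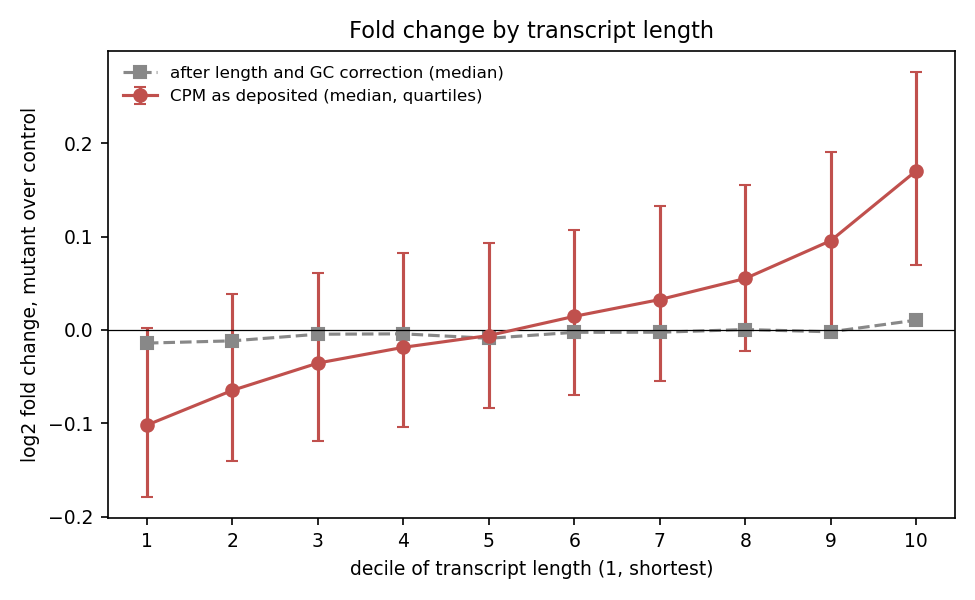
Median log2 fold change (mutant over control) of the tested genes in each decile of transcript length, with quartiles as bars, as deposited (red) and, as medians alone, after removal of each library's trend on length and GC content (grey). The deposited values run from -0.10 in the shortest to 0.17 in the longest decile, and the corrected ones lie between -0.01 and 0.01.

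Reported targets of the cluster were slightly higher, and none was called unpaired, over all genes or adjusted over the list alone. Of 32 measured members 10 rose and 0 fell paired by litter, among them Rbl2, a retinoblastoma-like pocket protein (45.1 ± 4.68 CPM in control and 57.2 ± 1.71 CPM in mutant kidneys, adjusted p = 0.203, 0.0140 paired), the receptor gene Tgfbr2 (70.0 ± 3.83 and 86.3 ± 7.48 CPM, 0.248, 0.0112 paired) and the nuclear receptor co-activator gene Ncoa3 (80.8 ± 9.63 and 101 ± 8.84 CPM, 0.265, 0.0114 paired). Cftr, a chloride channel gene, stood at 20.1 ± 2.72 CPM in control and 23.0 ± 1.16 CPM in mutant kidneys (adjusted p = 0.591, 0.149 paired). Its searched 3' UTR held no site of the 4 families. The pro-apoptotic gene Bcl2l11 had a log2 change of -0.16. The median was 0.17 (camera adjusted p = 0.000523, 0.000191 paired), and the adjusted p with an estimated correlation was 0.370. With the block and the length and GC correction the median was 0.06 (camera adjusted p = 0.0133, and an adjusted p of 0.617 with an estimated correlation). There 3 members rose and Bcl2l11 fell (adjusted p = 0.0413), and Tgfbr2 (0.129) and Ncoa3 (0.103) were no longer called.

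Messages with seed sites of the cluster in their 3' UTR were shifted upward as a class, by a small amount. The median log2 change of 4420 genes with a 7-base site of any of the 4 families exceeded that of 8429 genes without one by 0.0829, and by 0.0717, 0.0809 and 0.0908 in litters 1, 2 and 3 (SD 0.00957). None of 50 sets of control 7-mers gave as large a difference, although these too lay above 0, from 0.0429 to 0.0584. By family the difference was 0.0823 for miR-17/20a, 0.0544 for miR-18a, 0.0722 for miR-19 and 0.0837 for miR-92a, and 0, 2, 0 and 0 of 50 control 7-mers did as much. Without control library 2 it was 0.0516 for miR-17/20a and 0.0566 for any site, and without mutant library 2 it was 0.104 and 0.105. Camera gave an adjusted p of 8.25e-06 for any site (1.24e-06 paired) and, at the preset correlation, of 6.05e-08 to 0.0502 over the alternatives for seed sites. With an estimated correlation any site was not called in any setting tested, with an adjusted p of 0.148, of 0.0976 paired, of up to 0.289 with a library left out (mutant library 1), and of 0.302 with the block and the length and GC correction. Long 3' UTRs hold more sites, and among genes matched on 3' UTR length the difference was 0.0447. With the block and the length and GC correction it was 0.0318 for any site, 0.0337 for miR-17/20a, 0.0103 for miR-18a, 0.0296 for miR-19 and 0.0360 for miR-92a. For each of these 0 of 50 controls did as much, though for miR-18a the highest control reached 0.00966. For miR-18a, 12 of 50 controls did as much without control library 1 or without mutant library 2, before the correction. The camera adjusted p after the correction was 0.599 for miR-18a, 0.0744 for miR-19 and 0.0502 for miR-17/20a, for miR-92a and for any site, over the 5 sets of 7-base sites. Over 7-base and 8-base sets together it was 0.0430 for miR-17/20a, for miR-92a and for any site, so at the preset correlation these 3 calls rest on that choice, and with an estimated correlation none was made. Sites of 8 bases gave 0.0882 before and 0.0432 after the correction, with an adjusted p of 0.00485 after it. With an estimated correlation these had an adjusted p of 0.142 before and 0.262 after.

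**Figure D4:**
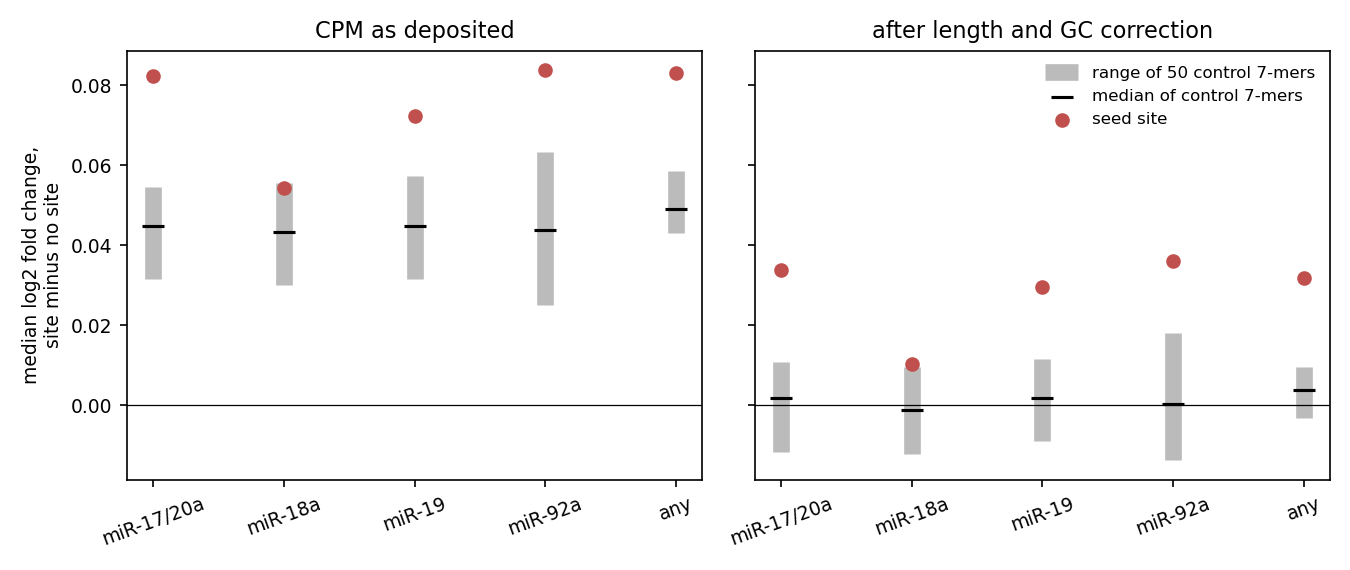
Difference in median log2 fold change (mutant over control) between genes with and without a 7-base seed site in the 3' UTR (red), for each family and for any site, beside the range (grey) and median (black) of 50 control 7-mers, for values as deposited (left) and after removal of each library's trend on length and GC content (right). For any site the difference is 0.0829 against controls of 0.0429 to 0.0584 as deposited, and 0.0318 against controls of -0.00309 to 0.00960 after the correction.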

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

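Tests with limma's voom, with a length and GC correction, with the block under median-ratio scaling or on litters 2 and 3 alone, and of the seed sites with an estimated correlation or adjusted over both site lengths were chosen after the results were seen. Six3 kept its direction and passed under every alternative in which it was tested, and the count of gene lists called by camera stayed between 10 and 13 except as given here. Pseudocounts of 0.1 and 1, no filter, median-ratio and trimmed-mean scaling, robust fitting without the trend and voom without the block gave 62 to 80 changed genes. With a filter of 5 CPM, which tests fewer genes, 53 changed, 33 of them higher. Read tests with edgeR and DESeq2 were planned for raw counts and not run, since the table holds CPM from which reads could only be recovered. At 1 CPM a value rests on 44 to 55 reads, which limits what can be seen of weakly expressed genes.

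The litter block gave 1574 changed genes, 1091 higher and 483 lower. With median-ratio scaling it gave 1502 (909 and 593), with the length and GC correction 828 (479 and 349), with voom 1550 (1067 and 483), and on litters 2 and 3 alone 381 (304 and 77). The correction without the block gave 162 (100 and 62). The block removes the difference between litters, which correlated within each litter across genes. For the targeted locus the log2 difference passed at 0.57 with the block (adjusted p = 0.0292), 0.56 with median-ratio scaling (0.0359), 0.60 with the correction (0.0230) and 0.57 with voom (0.0316), all with the block. Of the results followed through the block, 88 kept their direction and call, 48 passed in addition, and 1, the loop and distal tubule list, no longer passed. Beyond those given with each result, the block changed no camera call of a list. With an estimated correlation camera called 0 lists, and fry called 4 unpaired, Six2 and its neighbours, nephron progenitor, stroma and extracellular matrix. The calls lost by camera do not measure correlation alone. For stroma unpaired the estimate was -0.0282, below the preset 0.01, yet the unadjusted camera p went from 1.08e-07 to 0.00433. For nephron progenitor paired by litter the estimate was -0.0148, and p went from 4.47e-09 to 0.0233. Extracellular matrix and ribosomal proteins had higher estimates, 0.226 and 0.47 unpaired. Paired by litter fry called 3, nephron progenitor (adjusted p = 0.0167), stroma (0.0491) and tubular injury (0.0394, against 0.0822 unpaired). The extracellular matrix list no longer passed fry there (0.0525, against 0.0450 unpaired). For seed sites the difference of 0.0829 did not pass with an estimated correlation (adjusted p = 0.148). It was 0.0447 with genes matched on 3' UTR length and 0.0318 with the block and the length and GC correction (adjusted p = 0.0502). In both, part of the difference went with transcript or 3' UTR length, and for the other changes of call the cause was not tested.

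Leaving out 1 library or litter gave 1 to 100 changed genes, 0 to 67 higher and 1 to 33 lower. With libraries or litters left out, log2 changes that turned their direction ranged from -0.0941 to 0.27 for Upk3a, -0.85 to 0.16 for Upk1b, -0.25 to 0.0525 for Star, -0.0069 to 0.33 for the joined row of Insl3 and Jak3, -0.0837 to 0.20 for Ddx4, -0.54 to 0.0439 for Actc1, -0.0439 to 0.40 for Uty and -0.15 to 0.0899 for Hist1h2bc. List medians whose set test turned ranged from -0.0137 to 0.10 for Six2 and its neighbours, -0.0174 to 0.0776 for early nephron, -0.0074 to 0.0928 for podocyte, -0.35 to 0.24 for urothelium, -0.12 to 0.0191 for erythroid, -0.0116 to 0.0414 for hypoxia and glycolysis, -0.0103 to 0.18 for renin-angiotensin and 0.0037 to 0.53 for sex. On litters 2 and 3 with the block, the log2 change was -0.0941 for Upk3a, 0.0525 for Star and -0.0439 for Uty, and the median -0.0137 for Six2 and its neighbours and 0.0037 for sex. With the length and GC correction it was 0.0289 for Hist1h2bc, with or without the block, and the median was 0.0405 for urothelium and, with the block, 0.0301 for erythroid. Fry gave urothelium, with its median of 0.0348, the other direction. The hypoxia and glycolysis list, with a median of 0.0013 under median-ratio scaling and 0.0177 with the block, turned its test. No gene or list passed in a setting where it turned. Camera called urothelium lower without control library 1 (adjusted p = 0.0391) and without litter 1 (0.00397), and on litters 2 and 3 with the block it called urothelium (0.00571), erythroid (0.0362) and liver (0.0362) lower. The cause was not tested.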

Other observations

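The tests of reads shared between paralogs and of the number of families with a site, and every value after the length and GC correction, were chosen after results of this comparison had been seen. Genes of endothelium and of macrophages were slightly higher in mutant kidneys. Among 18 endothelial genes 0 were called unpaired, 1 rose adjusted over the list alone, and 5 rose paired by litter, among them the receptor gene Kdr (134 ± 1.02 CPM in control and 168 ± 8.83 CPM in mutant kidneys, adjusted p = 0.106, 0.00651 paired) and the cadherin gene Cdh5 (123 ± 8.21 and 149 ± 6.5 CPM, 0.00971 paired). The set had an adjusted p of 0.0178 by camera (0.00715 paired), and of 0.370 with an estimated correlation. It was 0.0847 without control library 1 and 0.145 without mutant library 2. In the macrophage and leukocyte list 0 of 14 genes were called unpaired and 1 rose paired, Mrc1, the mannose receptor gene (23.3 ± 3.12 and 30.8 ± 4.73 CPM, adjusted p = 0.315, 0.0208 paired). The median was 0.26 (camera adjusted p = 0.00350, 0.00719 paired), with an adjusted p of 0.370 with an estimated correlation, and of 0.0916 without mutant library 2. Proliferation genes were slightly lower, with a median of -0.07 over 38 members. Cell cycle genes Cenpa, Cdk1 and Ccnb1 were among the 5 that fell paired by litter, with log2 changes of -0.23, -0.21 and -0.21, while Mki67 had a change of 0.02. The set had an adjusted p of 0.00350 by camera (0.000737 paired), and of 0.308 with an estimated correlation. Of 19 genes of cystic kidney disease 0 were called unpaired and 6 rose paired, among them Pkd2, Pkhd1 and Bicc1, with log2 changes of 0.25, 0.26 and 0.27. The set had an adjusted p of 0.0194 by camera (0.00476 paired), and of 0.356 with an estimated correlation. It was 0.0655 without control library 2 and 0.122 with the block and the length and GC correction, where 1 member rose and Pkd2, Pkhd1 and Bicc1, with log2 changes of 0.16, 0.0410 and 0.18, were not called.

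The other lists were not called as sets by camera, and members are given where they passed. Paired by litter 11.4% of all tested rows were called, so a few paired calls do not set a list apart. Adjusted over the list alone and unpaired, 1 gene rose in tubular injury, 2 in renin-angiotensin, 1 in p53 and apoptosis and 1 in neural and Schwann, where 2 fell, 1 fell in skeletal muscle and 1 in liver, and 0 passed in the others. In tubular injury (15 genes, adjusted p = 0.0989) Vcam1, an adhesion molecule, was at 48.3 ± 8.69 CPM in control and 72.8 ± 2.42 CPM in mutant kidneys and rose paired by litter (adjusted p = 0.00365), as did Clu (0.00983), Cp (0.0395) and Sox9 (0.0407). The set passed without control library 1 (0.0391), without mutant library 3 (0.0379), and with the length and GC correction (0.00807, or 0.0110 with the block as well, where it was 0.516 with an estimated correlation). The peptidase genes Ace, Enpep and Mme rose paired in the renin-angiotensin list (7 genes, set adjusted p = 0.30), and Eda2r, Apaf1 and Cdkn1a in p53 and apoptosis (22 genes, 0.324). In hypoxia and glycolysis (21 genes, 0.95) Ndrg1 and Pfkfb3 rose and Pgk1 fell when paired. Elavl4, which encodes a neuronal RNA-binding protein, fell from 8.17 ± 1.59 to 3.07 ± 1.06 CPM (adjusted p = 0.0302, 0.00365 paired) in the neural and Schwann list (6 genes, set 0.194), where Nefl fell when paired (0.0315). With each of the 6 libraries left out in turn and no block, Elavl4 was called 3 times, with an adjusted p up to 0.189. The liver list (5 genes, 0.268) held Afp, the alpha-fetoprotein gene, which fell when paired (125 ± 4.38 and 93.1 ± 8.32 CPM, adjusted p = 0.00481), and the set passed without litter 1 (0.0257). In skeletal muscle (3 genes, 0.294) Mylpf fell when paired (1.77 and 0.861 CPM, adjusted p = 0.0304). No member was called in urothelium (7 genes, 0.889), erythroid (13 genes, 0.350), adrenal (3 genes, 0.153), gonad (3 genes, 0.624), immediate early and heat shock (15 genes, 0.30), replication-dependent histones (6 genes, 0.294) or sex (4 genes, 0.0509), and 0 mitochondrial transcripts were in the table. The sex list passed with control library 2 (0.00828), control library 3 (0.0113), mutant library 2 (0.00801) or mutant library 3 (0.0461) left out, without litter 2 (0.00146) or litter 3 (0.0122), and with a filter of 5 CPM (0.0367). Median and mean differed in sign for urothelium (0.03 and -0.01), erythroid (-0.07 and 0.02) and liver (-0.13 and 0.04), and camera pointed down in each.

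Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many as 77 changed genes, the real one, the highest other gave 4, and 10 splits are too few for a share under 0.05. Among the 4 splits that part every litter, the litter block called 1574 genes in the real split and 0 in each of the others, while the split that sets control library 1 and mutant libraries 1 and 3 against the rest had 2461 genes at an unadjusted p below 0.05, against 1551 in the real split, which points to further structure among the libraries. This split also parted the libraries by their relation of expression to GC content. Its rho was -0.539, -0.616 and 0.0204 in control library 1 and mutant libraries 1 and 3. In control libraries 2 and 3 and mutant library 2 it was 0.422, 0.258 and 0.596. Both libraries of litter 1 were lowest, and whether differences between litters follow GC content was not tested. Xist stood at 624 CPM in control library 1 and at no more than 0.255 CPM elsewhere, and the Y-linked gene Ddx3y at 53.8 CPM there and 82.7 to 125 CPM elsewhere. The Y-linked genes Eif2s3y, Kdm5d and Uty were at 54.6, 39.6 and 37.8 CPM in control library 1. That library thus held both Xist and Y-linked reads, and whether it joined embryos of both sexes was not tested. Of the called genes 5.19% lie on X or Y, a share not set against that of all tested genes. From the sex list 0 were called, but Xist was not among its 4 tested genes. Without control library 1, where every library left was low in Xist, 100 genes were called, 68 of them among the 77. This argues against sex as the source of change in those 68 genes. A difference in blood is argued against by the erythroid median of -0.0714. For adhering adrenal, gonad, liver, muscle or nerve tissue the smallest adjusted p of a list was 0.153. Elavl4 is among the called genes, however, and Alb, of the liver list, stood at 11.6 CPM in mutant library 3 and at 0.528 to 2.37 CPM elsewhere. Adhering tissue therefore stays open.

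Six3 expression in mutant kidneys may come from extra copies of genes carried by the Six2-TGC transgene, which needs Six3 in every mutant and no control kidney, if the controls lacked the transgene. The lowest mutant value was 15.3 CPM and the highest control value 0.0454 CPM, as that explanation requires, although the other measured neighbours of Six2 were not called. Loss of repression by the cluster needs a site in Six3, and its searched 3' UTR of 2272 bases holds a site of 1 of the 4 families, but 34.3% of all searched genes hold a site. The median log2 change of genes with a site exceeded that of genes without one by 0.0829, against a change of 5.13 for Six3. A shift of the size seen in the class would therefore not account for Six3. How far a single gene with a site can rise was not tested. Reads shared between the paralogs are argued against, since Six3 reads were 0.0287% of the Six2 reads in control kidneys. The control label names no transgene, so the transgene and the deletion both stay open.

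The trend on transcript length could come from a difference between the libraries in how RNA was kept or fragmented. For the extracellular matrix list, whose median was 0.195 after the trend was removed (0.289, 0.20 and 0.107 in litters 1, 2 and 3), and for the ribosomal protein list (-0.152 after it, and -0.164, -0.142 and -0.138 by litter), such a difference is argued against as the whole cause only as far as it follows annotated length. The longest annotated transcript need not be the one expressed, so an effect of the expressed length could remain in both lists. More stroma in mutant kidneys predicted a stromal median above 0.1 after the correction, and it was 0.198 (camera adjusted p = 7.71e-06, and 0.451 with an estimated correlation), with 0.233, 0.135 and 0.160 by litter. After the correction Acta2, Tagln, Pdgfrb and Cspg4, genes of smooth muscle and pericytes, had log2 changes of 0.05, 0.02, -0.01 and -0.04, and Rgs5 of -0.40 (adjusted p = 0.0904), and none of these was called. A higher share of stroma, stronger expression within stromal cells, and a length effect on the rest of the genes stay open.

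One hypothesis was that genes with sites of more families of the cluster shift further. After the length and GC correction and with the block, the median log2 change was -0.0149 for 8429 genes with a site of 0 families, 0.0121 for 3221 genes with 1, 0.0284 for 959 genes with 2 and 0.0276 for 240 genes with 3 or 4. Among the 4420 genes with a site of at least 1 family, the rank correlation of the corrected change with the number of families was 0.0448, and 0 of 50 sets of control 7-mers gave as much, the highest being 0.0116. The correlation is weak, and these medians and the corrected differences had been seen when the test was chosen.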
